A study of Mus musculus with 10 samples.

How the data were processed

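RNA of sorted mouse CD4 T cells was measured on 10 Affymetrix mouse arrays, 1 per group. Per the labels' protocols, cells were enriched with magnetic beads and sorted by flow cytometry, RNA was extracted with Stat-60, and biotinylated cRNA was made in 2 rounds of amplification with a MessageAmp II kit. Amplification in 2 rounds starts from the 3′ end and shortens the product, so probe sets far from the 3′ end lose signal first. The deposited table holds log2 expression values of 45101 probe sets, which the authors normalized together over the 10 arrays, per the series' design text, although the arrays came from separate experiments. The software and the methods of background correction, probe summary and normalization are not given in the sources used here. That the deposited values are on a log2 scale was read from their range (array medians of 3.04 to 3.22), and none were missing. The labels of untreated arrays do not say whether those mice received the vehicle of the IL-2 injections.

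Probe sets were named through the platform annotation, which can be old, and symbols were updated by Entrez ID to the gene table of the assembly GRCm38.p6, used only for names and for which genes neighbour each other. Of the probe sets 34958 had 1 gene, 932 several and 9211 none listed, 51 of the last being control probe sets. Of those with 1 gene 34754 were matched by Entrez ID. Probe sets with 1 gene, 18194 genes, were kept where at least 1 array was at or above its own median over all probe sets, and each gene was read by the probe set with the highest mean over the 10 arrays, which left 11938 genes. Probe sets of a gene can disagree, and the alternatives below test this choice. No position of a probe within its transcript was used.

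Where every array of the lower side of a comparison lay below its median over all probe sets, as for 53 of the 164 largest differences named, the gene was taken as not above background there. The printed log2 difference is then the measured one, and a fold given as "at least" sets the higher side against that median, or the gene's own value if higher, per array. Groups were taken from the sample titles. Over the 6 arrays of GFPfoxp3, GFPko and CD25pos cells with and without IL-2, an additive model of population and IL-2 was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). Its 2 residual degrees of freedom come from the interaction of population and IL-2. The prior held 2.23 degrees of freedom with an SD of 0.129. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Standard errors are limma's moderated ones. The other 9 comparisons hold 1 array on each side and were described by the number of genes that differ at least 2-fold, with no test. Where 2 comparisons share a control, 100 sets of unchanged groups were simulated against it with the spread fitted over those 6 arrays. Neither shared control, CD25neg or MigR1_empty, was among them.

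The 24 gene lists covered regulatory T cell genes, naive T cell genes, effector cytokines, helper lineage factors, inhibitory and activation receptors, cytotoxic genes, migration receptors, IL-2 and STAT5 targets, the cell cycle, ribosome biogenesis, glycolysis, cholesterol synthesis, cAMP machinery, cAMP-responsive genes, immediate early genes, interferon-induced genes, apoptosis, T cell receptor signalling, markers of B cells, myeloid cells, CD8 and NK cells, erythroid cells and plasma cells, and neighbours of Foxp3 on the X chromosome. Some genes are in several lists, such as Gzmb and Pde3b. Il2ra, Il2rb, Socs2, Gzmb and Tnfrsf4 are in both the regulatory T cell list and the list of IL-2 and STAT5 targets. Lists were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation and with fry. In pairs of single arrays the median of a list was ranked among 10000 random lists matched on mean expression in 20 bins, which describes these arrays and tests nothing. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 8 largest increases and the 8 largest decreases among calls that went the same way in every pair, the 6 largest of each in pairs of single arrays among genes brighter than the array median, up to 4 members of each list by size of difference, and Foxp3 and Pde3b.

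Alternatives were quantile normalization, centring of each array on its median over the kept genes, no filter on dim genes or a filter on the mean, the mean of all probe sets of a gene, leaving out probe sets whose identifiers mark possible cross-matching, an intensity trend with robust variance, all 10 arrays in the fit, no population term, leaving out each population or IL-2 state, a 3-fold threshold, and a spread borrowed from the 6 modelled arrays for the single pairs. Calls with the borrowed spread also had to differ at least 2-fold. For IL-2 in single populations, and where an IL-2 state was left out, t statistics were computed from limma's spread and degrees of freedom of the full fit. Counting genes that differ at least 2-fold in every pair was added after seeing the data. The steps were tested on simulated data of 11938 genes with 50 genes changed per fold size. For the IL-2 effect 6%, 48%, 94% and 98% of genes changed 1.5-, 2-, 4- and 8-fold were called, with 4 of 11738 unchanged genes. For GFPfoxp3 against GFPko the shares were 0%, 14%, 82% and 92%, with 6 of 11738. Of 20 simulated lists for the IL-2 effect, camera called 10 of 10 shifted 2-fold and 0 of 10 unshifted, with either correlation. The simulated genes were independent of each other, while the estimated correlation was, for example, 0.604 in the ribosome biogenesis list. The simulated lists therefore do not check calls for lists whose genes move together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.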

Results

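Gene expression was measured on Affymetrix mouse oligonucleotide arrays in CD4 T cells sorted from the pooled lymph nodes and spleen of mice, with 10 arrays in 10 groups and therefore 1 array per group. Foxp3 is the transcription factor that marks regulatory T cells. In the Foxp3 gfp line it is made as a fusion with green fluorescent protein (GFP), so that GFP marks cells holding the protein. In the gfpko line the locus makes GFP in place of Foxp3. The gene lies on the X chromosome, so each cell of a heterozygous female uses 1 of its alleles and the GFP-positive cells of gfpko/wt females read the locus without making Foxp3. From gfp/gfp mice came GFP-negative cells without CD25 (CD25neg), GFP-negative cells with CD25, the alpha chain of the IL-2 receptor (CD25pos), and GFP-positive cells (GFPfoxp3). GFP-positive cells from gfpko/wt mice formed GFPko. CD25pos, GFPko and GFPfoxp3 cells were also taken from mice given IL-2, at 50 ng per g in each of 4 injections over 24 h, with isolation 30 min after the last. The other 3 arrays came from CD25-positive CD4 cells, labelled as from C57BL/6 mice, transduced with the retroviral vector MigR1, which carries GFP. The vector was empty (MigR1_empty), or carried PDE3B, a phosphodiesterase that breaks down cAMP (MigR1_PDE3B), or PDE3B with the substitution H801A (MigR1_PDE3B_H801A). These cells were transferred into mice lacking T cell receptor alpha, and after 3 weeks GFP-positive cells bearing GITR, a surface receptor abundant on regulatory T cells, were sorted.

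Foxp3, read by 1 probe set, lay at a log2 level of 2.45 in CD25neg, 3.90 in CD25pos and 2.85 in CD25pos cells after IL-2. It reached 8.33 in GFPko and 9.39 in GFPko after IL-2, 10.86 in GFPfoxp3 cells in both states, and 11.52, 11.26 and 11.29 in the empty, PDE3B and H801A vector arrays. Since the place of this probe set relative to the GFP insertion is not given in the sources used here, its signal in GFPko cells shows a transcript of the locus and is no check of the missing protein. Pde3b, also read by 1 probe set, was abundant in cells without Foxp3, at 11.73 in CD25neg, 11.62 in CD25pos and 11.63 in CD25pos after IL-2. The level was 10.22 in GFPko and 9.92 in GFPko after IL-2, and only 6.06 and 5.90 in GFPfoxp3 cells without and with IL-2. The transduced cells gave 7.43 with the empty vector, 6.91 with PDE3B and 7.54 with H801A, so the array labelled PDE3B did not show a higher level. This probe set may lie outside the transduced sequence and then checks nothing about transduction. Whether the vectors raised PDE3B is therefore unverified here, and PDE3B and H801A name these arrays by their labels only. Cd4 and GFP were used in every sort, GFP standing for the Foxp3 locus in the cells that were not transduced. CD25 (Il2ra) was used for the GFP-negative cells and for choosing the cells to transduce, and GITR (Tnfrsf18) for the final sort of the transduced ones. These levels are therefore properties of the selection there, at least in part.

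**Figure D1:**
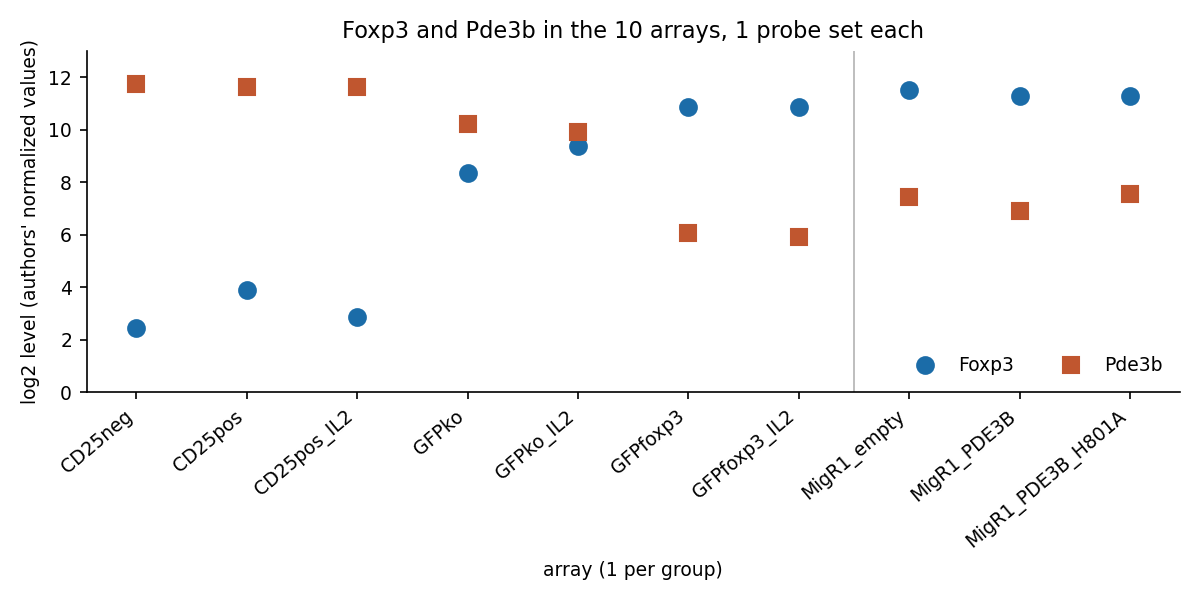
Log2 levels of Foxp3 (circles) and Pde3b (squares) in the 10 arrays, 1 point per array, with the transduced cells right of the grey line. Pde3b lies between 9.92 and 11.73 in the 5 arrays of CD25neg, CD25pos and GFPko cells and at 5.90 and 6.06 in GFPfoxp3 cells, where Foxp3 is at 10.86.

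The 7 arrays of sorted cells and the 3 of transduced cells stood apart. The difference between the 3′ and 5′ control probe sets of Actb, which grows as RNA or cRNA becomes shorter, was 2.70 to 3.80 log2 units in the sorted cells and 5.87, 6.38 and 5.95 with the empty, PDE3B and H801A vectors. Within the sorted cells the 3 arrays after IL-2 (2.86 in CD25pos, 2.76 in GFPko and 2.70 in GFPfoxp3) lay below their untreated partners (3.80, 3.69 and 3.07). No group had a replicate array, and the number of arrays limits the precision of every value. Where limma was used, the spread came from how differently the 3 populations responded to IL-2, so its p-values measure how alike a change was between populations or between IL-2 states, not how repeatable it was between animals.

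GFPfoxp3 and GFPko cells both read the Foxp3 locus, and their comparison asks which genes differ when the protein is also made. The largest increases with the protein included receptors and effector molecules. Klrg1, an inhibitory lectin-type receptor, was 118-fold higher (log2 difference 6.88, SE 0.303, adjusted p = 0.0052) and Itgae, the CD103 integrin chain that binds E-cadherin, 19.9-fold (4.31, SE 0.107, adjusted p = 0.00371), each higher in both pairs of arrays. Gzmb, the cytotoxic protease granzyme B, was higher by 5.21 (SE 0.291, adjusted p = 0.00792). F13a1 (5.42), Nrn1 (4.99), Fcmr (4.54), Epcam (4.13) and Cybb (4.09) completed the 8 largest increases. On the other side, the cytokine Il17a fell by 4.10 log2 units (SE 0.438, adjusted p = 0.021), Ccl20, the chemokine ligand of CCR6, fell by 4.73, and the cytokine Il21 fell by 3.90. Pde3b fell by 4.09 (17.0-fold, SE 0.121, adjusted p = 0.00447), beside BC018473 (-5.39), Ctse (-4.19), Cxcr6 (-4.00) and St6galnac2 (-3.81). Foxp3 transcript itself differed by 2.00 (SE 0.525, adjusted p = 0.106) and did not pass. F13a1 and Fcmr in GFPko cells and BC018473 and St6galnac2 in GFPfoxp3 cells lay below the array medians on both arrays, so these differences rest on background and their order is not settled. They amount to at least 26.1-fold and 19.2-fold higher and at least 37.2-fold and 11.4-fold lower. On 1 of the 2 arrays of their lower side Gzmb, Il17a and Il21 were below the array median too, as were Aurka and Cenpe among the list genes, so the sizes of these differences rest in part on background.

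Among the gene lists, the 28 measured genes characteristic of regulatory T cells held 18 that were higher and 0 lower with Foxp3 protein (22 and 0 adjusted over the list alone) and a median of 1.55. Foxp3 is in this list, and GFP made from its locus was the gate of both populations. Ebi3, a subunit of the suppressive cytokine IL-35, was among them at 3.53 (SE 0.223, adjusted p = 0.00835). Camera gave this list an adjusted p = 1.5e-12, and adjusted p = 0.529 with an estimated correlation. Of the 29 cell cycle genes 16 were higher and 0 lower (21 and 1 adjusted over the list alone, median 1.17), among them Ccnb2, a mitotic cyclin (3.05), Aurka, a spindle kinase (2.83), and Cenpe, a kinetochore motor (2.16). The list's adjusted p was 1.8e-10, and the adjusted p was 0.529 with an estimated correlation. Of the 12 naive T cell genes 7 were lower and 0 higher (9 and 1 adjusted over the list alone, median -0.93), including Dapl1 (-2.23), Igfbp4 (-1.77) and the cytoskeletal Actn1 (-1.34) beside Pde3b. The list's adjusted p was 1.9e-06, with adjusted p = 0.546 for an estimated correlation. Cytokines of effector cells held 3 that were lower and 0 higher of 9 (3 and 0 adjusted over the list alone), namely Il17a, Il21 and Il4 (-3.59, at background in GFPfoxp3 cells and at least 6.55-fold lower), with a list adjusted p = 0.0111 and adjusted p = 0.546 with an estimated correlation.

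Receptors for migration went both ways, with 5 higher and 2 lower of 13 (6 and 2 adjusted over the list alone, median 0.89). Gpr15, a homing receptor for the large intestine (2.14), and Ccr8 (2.12, at background in GFPko cells and at least 2.63-fold higher) stood on one side and Cxcr6 on the other. That list had an adjusted p = 0.00849, and adjusted p = 0.546 with an estimated correlation. Interferon-induced genes were mostly lower, 4 against 1 higher of 18 (11 and 4 adjusted over the list alone, median -0.56). Oasl2 (-1.99) and Ifit1 (-1.37), which act against viral RNA, were lower and Gbp3 (1.45) was higher, with a list adjusted p = 0.00386 and adjusted p = 0.529 with an estimated correlation. The glucose transporter Slc2a3 (2.30) and the glycolytic enzyme Tpi1 (1.58) were the 2 of 12 glycolysis genes that were higher (3 adjusted over the list alone). The list's adjusted p was 0.00875, and adjusted p = 0.592 with an estimated correlation. Of 15 immediate early genes only Fos, a stress- and activation-induced transcription factor, was lower at this threshold (-2.17, 3 adjusted over the list alone), with a list adjusted p = 0.0164 and adjusted p = 0.546 with an estimated correlation. None of 6 myeloid markers passed singly (0 adjusted over the list alone), while their list had a median of -0.44 and an adjusted p = 0.039, and adjusted p = 0.592 with an estimated correlation. Untreated and after IL-2, the median level of these markers was 2.90 and 2.88 in GFPfoxp3 and 3.02 and 3.42 in GFPko cells. The medians of these arrays were 3.04 to 3.11, so the shift rests in part on background.

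Within the machinery of cAMP signalling 3 of 18 genes were higher and 3 lower (3 and 5 adjusted over the list alone). Besides Pde3b, the phosphodiesterase Pde7a was lower (-1.48), while the phosphodiesterase Pde2a (1.94) and Prkar1b, a regulatory subunit of protein kinase A (1.57), were higher. Prkar1b was read by a probe set that can cross-match, so its difference is uncertain. Camera did not call this list (adjusted p = 0.221, and 0.765 as the adjusted p with an estimated correlation). Crem, a cAMP-responsive transcription factor, was higher by 1.77 and belongs to the separate list of cAMP-responsive genes. That list had 1 of 12 higher and 0 lower, and camera did not call it (adjusted p = 0.857, and 0.917 as the adjusted p with an estimated correlation). Markers of B cells moved with the comparison: Cd74 (3.11), Ighm (2.03) and Cd79b (1.65) were higher in GFPfoxp3 cells, 3 of 8 measured with 0 lower (3 and 1 adjusted over the list alone), which camera did not call as a list (adjusted p = 0.301, and 0.601 as the adjusted p with an estimated correlation) and fry did (adjusted p = 0.0181). The gamma chain segment Trgv4, looked up after the data were seen, lay higher in GFPko cells. Untreated and after IL-2 it was at 8.48 and 9.25 there and at 5.83 and 6.17 in GFPfoxp3 cells. Another probe set gave 7.64 and 7.73 against 5.09 and 5.39, and a dim one 3.33 and 3.24 against 3.15 and 3.15. Trgv1 was at 5.11 and 8.10 against 5.44 and 6.09. The Actb 3′ to 5′ difference was 3.07 in GFPfoxp3 and 3.69 in GFPko cells without IL-2 and 2.70 and 2.76 with it.

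Over 11938 genes limma called 650 higher and 242 lower in GFPfoxp3 than in GFPko cells at an adjusted p under 0.05, and 535 genes differed at least 2-fold the same way in both pairs, 403 higher and 132 lower. With each array centred on its median over these genes the calls numbered 708 higher and 671 lower, 51.3% higher against 72.9%, and 820 of the 892 genes were shared. With no filter on dim genes 382 were called, 353 of them shared, and with only the untreated or only the IL-2-treated pair 181 and 188. Of 946 genes that differed at least 2-fold in untreated mice, 915 (96.7%) differed the same way after IL-2, with a correlation across genes of 0.722 (genes are not independent replicates). Calml3 alone differed at least 2-fold in opposite directions in the 2 pairs, a gene singled out after its values were seen. The 2 mouse lines also differ in their number of backcross generations, per the labels.

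**Figure D2:**
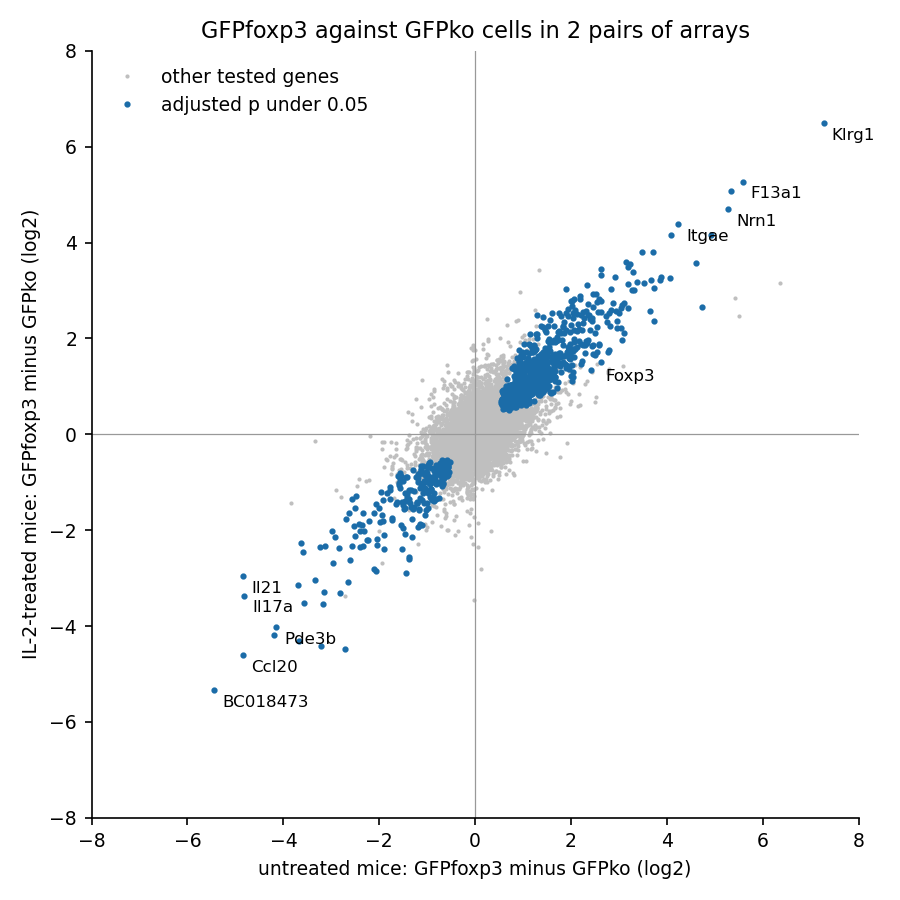
Log2 difference between GFPfoxp3 and GFPko cells for each of 11938 genes, in untreated mice (x) and IL-2-treated mice (y), with genes at an adjusted p under 0.05 in blue and the others in grey. Klrg1 lies farthest to the upper right and BC018473 to the lower left, and 915 of the 946 genes at least 2-fold apart in untreated mice keep their direction.

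GFPfoxp3 cells were next set against CD25pos cells of the same mouse line, which carry CD25 and no GFP. Apart from Foxp3 (7.49), used in the sort, the largest increases were in Gbp2b, an interferon-inducible GTPase (6.54, SE 0.236, adjusted p = 0.00479), Klrg1 (6.13, SE 0.303, adjusted p = 0.00516) and Itgae (5.44, SE 0.107, adjusted p = 0.00402), followed by F13a1 (4.71), Fcmr (4.50), Neb (4.38) and Ncmap (3.86). The chemokine receptor Cxcr6 was 106-fold lower (-6.72, SE 0.237, adjusted p = 0.00479) and Pde3b 50.1-fold (-5.65, SE 0.121, adjusted p = 0.00402). Klrd1, the CD94 receptor chain of NK and cytotoxic cells, was lower by -6.05. Lypd6b (-5.53), Atp8b4 (-4.89), Il4 (-4.84), the T-box factor Eomes (-4.70) and Il21 (-4.63) were the other large decreases. On both arrays of the lower side Gbp2b, Fcmr, Neb, Lypd6b, Atp8b4 and Il4 lay below the array medians, and Foxp3, F13a1, Klrd1, Il21, Gpr15, Gzmk and Prkar1b did on 1 of 2. Their order is therefore not settled, and the first 6 amount to at least 67.4-fold, 19.4-fold and 17.2-fold higher and at least 37.8-fold, 24.4-fold and 15.6-fold lower. Gene for gene, 25 of 28 regulatory T cell genes were higher and 0 lower (28 and 0 adjusted over the list alone, median 2.65), with Gpr83 at 3.76. The list had an adjusted p = 7.1e-25, and adjusted p = 0.580 with an estimated correlation. The same adjusted p, 0.580 with an estimated correlation, applied to each list called in this comparison.

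Targets of IL-2 and STAT5 held 7 of 19 that were higher and 0 lower (10 and 2 adjusted over the list alone, median 1.07, adjusted p = 8.8e-06, and adjusted p = 0.580 with an estimated correlation), such as Tnfrsf4, the costimulatory receptor OX40 (2.81), and the transcription factor Nfil3 (2.78). Tnfrsf4 is among the genes this list shares with the regulatory T cell list, so the results of these lists are not independent. Effector cytokines were lower in 5 of 9 and higher in 0 (5 and 0 adjusted over the list alone, median -0.55, adjusted p = 4.7e-04, and adjusted p = 0.580 with an estimated correlation), with Il2 at -4.05 (at background in GFPfoxp3 cells, at least 11.8-fold lower) and Ifng at -3.34 beside Il4 and Il21. Naive T cell genes were lower in 7 of 12 (8, with 1 higher, adjusted over the list alone, median -0.92, adjusted p = 1.8e-04, and adjusted p = 0.580 with an estimated correlation), Dapl1 by -3.75. Ribosome biogenesis genes were lower in 4 of 18 (12 adjusted over the list alone, median -0.85, adjusted p = 1.1e-06, and adjusted p = 0.580 with an estimated correlation), including Polr1b, a subunit of RNA polymerase I (-1.41). Of 8 markers of CD8 and NK cells 3 were lower (4 adjusted over the list alone, median -0.64, adjusted p = 0.00105, and adjusted p = 0.580 with an estimated correlation), Klrk1 by -2.24 (at least 2.72-fold) beside Klrd1 and Eomes. Cytotoxic genes divided into 4 lower and 2 higher of 10 (5 and 2 adjusted over the list alone, median -1.34, adjusted p = 0.0292, and adjusted p = 0.580 with an estimated correlation). Fasl, the death ligand (-4.26), Nkg7 (-3.37) and Gzmk (-3.30) were lower while Gzmb (2.58) was higher. Migration receptors held 4 higher and 1 lower of 13 (7 and 1 adjusted over the list alone, median 0.47, adjusted p = 0.0171, and adjusted p = 0.580 with an estimated correlation), with Gpr15 at 3.37 and Ccr8 at 2.14 (at least 2.66-fold). Markers of B cells moved with this comparison too, 3 of 8 being higher and 0 lower (3 and 1 adjusted over the list alone, median 0.01), namely Cd79b (3.27), Cd74 (2.88) and Ighm (0.98). Camera did not call them as a list (adjusted p = 0.233, and adjusted p = 0.580 with an estimated correlation), while fry did (adjusted p = 0.017). In the cAMP machinery Prkar1b, read by a probe set that can cross-match, was higher (2.98). Pde7a (-2.46) and Prkar2a (-1.20), another regulatory subunit of protein kinase A, were lower beside Pde3b. Limma called 630 genes higher and 412 lower, and 373 and 234 differed at least 2-fold in both pairs. With no filter on dim genes 609 were called, 546 of them shared, and with a single pair 238 and 260. The 2 pairs correlated at 0.857 across genes.

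GFPko cells, which read the Foxp3 locus without its protein, were compared with CD25pos cells as well. Gbp2b (5.76, SE 0.236, adjusted p = 0.011), BC018473 (5.33, SE 0.102, adjusted p = 0.005), Ccl20 (4.59, SE 0.117, adjusted p = 0.00557) and Il17a (3.64, SE 0.438, adjusted p = 0.0378) were higher, as were Foxp3 transcript (5.49), the Wnt secretion factor Wls (4.32), Ctse (4.04) and the guanylate cyclase subunit Gucy1b1 (3.88). The chemokine Ccl5 was 117-fold lower (-6.87, SE 0.861, adjusted p = 0.0395). Also lower were Klrd1 (-5.38), Eomes (-5.17), Tbx21, which encodes T-bet (-4.79, SE 0.16, adjusted p = 0.00877), Zbtb16, which encodes PLZF (-4.08), Klrc1 (-3.96), Il17rb (-4.90) and Cxcr3 (-3.86). Gbp2b and BC018473 in CD25pos cells and Zbtb16 and Klrc1 in GFPko cells lay below the array medians on both arrays, so they amount to at least 39.2-fold and 36.6-fold higher and at least 11.9-fold and 13.3-fold lower, in no settled order. Foxp3, Klrd1, Il17rb, Aurka, Cenpe, Gzmb and Gzmk were below it on 1 of the 2 arrays of their lower side. Pde3b was lower by -1.56 (SE 0.121, adjusted p = 0.0207), a smaller decrease than in GFPfoxp3 cells.

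The cytotoxic list held 6 lower and 0 higher of 10 (7 and 0 adjusted over the list alone, median -2.23), including Nkg7 (-3.75), Fasl (-3.09) and Gzmk (-3.06). Its adjusted p was 1.3e-06, and adjusted p = 0.387 with an estimated correlation. Cell cycle genes were lower in 11 of 29 and higher in 0 (27 and 0 adjusted over the list alone, median -1.02, adjusted p = 7.0e-15, and adjusted p = 0.387 with an estimated correlation), with Aurka at -2.01 and Cenpe at -1.64. Interferon genes were higher in 3 of 18 (13 adjusted over the list alone, median 0.58, adjusted p = 4.8e-09, and adjusted p = 0.387 with an estimated correlation), namely Usp18 (1.43), Isg20 (1.06) and Ifit1 (1.01). Immediate early genes were higher in 4 of 15 (6 adjusted over the list alone, median 0.36, adjusted p = 2.0e-05, and adjusted p = 0.387 with an estimated correlation), Fos by 3.01 and Jun by 2.59. Regulatory T cell genes were higher in 9 and lower in 3 of 28 (15 and 5 adjusted over the list alone, median 0.96, adjusted p = 1.3e-06, and adjusted p = 0.510 with an estimated correlation). Ikzf4, a partner of Foxp3, was higher (2.70) and Gzmb lower (-2.63). Targets of IL-2 and STAT5 held 3 higher and 1 lower of 19 (8 and 2 adjusted over the list alone, median 1.05, adjusted p = 4.5e-05, and adjusted p = 0.510 with an estimated correlation). Glycolysis genes were lower in 3 of 12 (8 adjusted over the list alone, median -0.54, adjusted p = 5.5e-05, and adjusted p = 0.510 with an estimated correlation), among them Hk2 (-1.36) and Tpi1 (-1.32). Ribosome biogenesis genes were lower in 4 of 18 (5 adjusted over the list alone, median -0.50, adjusted p = 4.5e-05, and adjusted p = 0.541 with an estimated correlation), with Odc1 (-1.47), the first enzyme of polyamine synthesis, and Wdr12 (-1.14). Klrd1, Eomes and Klrk1 (-2.20, at least 2.65-fold) were the 3 of 8 CD8 and NK cell markers that were lower (3, with 1 higher, adjusted over the list alone, median -0.47, adjusted p = 0.0436, and adjusted p = 0.536 with an estimated correlation). The Actb 3′ to 5′ differences of these arrays were 3.69 and 2.76 in GFPko and 3.80 and 2.86 in CD25pos cells, untreated and after IL-2. In all, 149 genes were called higher and 267 lower, and 128 and 237 differed at least 2-fold in both pairs. Centred on their medians, the arrays gave 446 higher and 418 lower, 51.6% higher against 35.8%, with 412 of the 416 genes shared, and single pairs gave 9 and 13 calls. With no filter on dim genes 33 were called, all among the 416. Of 802 genes at least 2-fold apart in untreated mice, 724 (90.3%) kept their direction after IL-2.

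Over these 3 comparisons and that of IL-2, none of the 30 list calls made with camera's preset correlation held with an estimated one, the lowest such adjusted p being 0.387. Fry, whose p tests whether a list's genes move on balance in 1 direction and compares them with no other genes, called 27. In 17 of 96 list results the median, the mean and camera's direction differed in sign, and 0 of these were calls.

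Each untreated population was also compared with CD25neg cells, the conventional cells without either marker, as single arrays without a test. All 28 regulatory T cell genes were at least 2-fold higher in GFPfoxp3 cells (median 4.73), 23 in GFPko (2.83) and 23 in CD25pos (2.02), so that a large part of this list was also higher in cells without Foxp3 protein. All 3 medians lay at the 100th percentile of 10000 random lists matched on expression. Besides Foxp3 and Il2ra of the sort, GFPfoxp3 cells were highest in Itgae (7.05), Klrg1 (6.88), Gbp2b (6.57) and Ctla4, the inhibitory receptor for B7 molecules (6.49), and lowest in Lypd6b (-6.17), Pdlim4 (-6.14), Dapl1 (-6.09), Klrd1 (-6.01), Atp8b4 (-5.79) and Pde3b (-5.67). GFPko cells were highest in Ccr6, the receptor of CCL20 (6.30), Gbp2b (6.16), the carboxypeptidase Cpe (6.06) and the signalling inhibitor Socs2 (5.96), with Il17a at 4.85, and lowest in Ccl5 (-6.79), Pdlim4 (-6.11), Klrd1 (-5.84), App (-5.24), Rab6b (-5.05) and Atp8b4 (-4.78). CD25pos cells were highest in Lad1 (4.93), Bcat1 (4.76), Tk1, a thymidine kinase of S phase (4.61), Cdca5 (4.56) and Socs2 (4.53), and lowest in Pde5a (-3.26), Cd55 (-2.91), Gm9222 (-2.51), Il1rl2 (-2.43), Dapl1 (-2.33) and Dntt (-2.20). Below the median of the array on the lower side, and so with differences that rest on background and in no settled order, were Foxp3, Gbp2b, Lypd6b, Pdlim4, Klrd1 and Atp8b4 for GFPfoxp3, Foxp3, Gbp2b, Pdlim4, Klrd1 and App for GFPko, and Bcat1, Tk1, Cdca5 and Pde5a for CD25pos. The median of the cell cycle list was 2.12 higher in GFPfoxp3, 2.10 in CD25pos and 0.68 in GFPko cells, with 20, 25 and 12 of 29 genes at least 2-fold higher. Effector cytokines were higher in CD25pos (median 1.06), with Il4 at 3.0, Il21 at 2.91 and Il2 at 2.72, and ribosome biogenesis genes were higher there too (0.86). Helper lineage factors (median 1.55, 100th percentile, Tbx21 at 1.94) and cytotoxic genes (0.90, 100th percentile, Nkg7 at 2.43) lay above random lists in CD25pos. Helper lineage factors also did in GFPfoxp3 (1.29, 100th percentile) but not in GFPko (0.00, 65.02nd percentile), while cytotoxic genes lay below random lists in GFPfoxp3 (-0.59, 0.06th percentile) and GFPko (-1.51, 0th percentile). Beside these, markers of CD8 and NK cells had a median of 0.27 in CD25pos (98.87th percentile, 0.15 when centred), with Eomes at 3.28. Klrk1 (2.18) and Tyrobp (1.32) were at background in CD25neg and amount to at least 3.01-fold and at least 1.31-fold higher. In GFPfoxp3 their median was -0.19 (1.43rd percentile, -0.29 when centred). Naive T cell genes were lower in each population, with medians of -1.46, -0.64 and -0.57 in GFPfoxp3, GFPko and CD25pos.

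At least 2-fold higher and lower than in CD25neg were 873 and 433 genes in GFPfoxp3, 469 and 334 in GFPko and 663 and 202 in CD25pos. Centring moved the median of all genes to -0.114 in GFPfoxp3 and to -0.11 in CD25pos, and for CD25pos changed the split to 550 and 317 (63.4% higher against 76.6%). The list medians named here kept their sign. These comparisons share the CD25neg array. GFPfoxp3 and GFPko had 318 higher and 162 lower genes in common, where unchanged groups against 1 shared control gave 6.38 and 5.56 in simulation and independent lists of these sizes would share 34.3 and 12.1. Their differences correlated at 0.638 across genes (0.5 simulated), with a covariance of 0.308 against 0.0307 simulated. GFPfoxp3 and CD25pos shared 359 and 121 genes (6.05 and 5.48 simulated, 48.5 and 7.33 if independent), with a correlation of 0.604 (0.5 simulated) and a covariance of 0.280 (0.0307 simulated). For GFPko and CD25pos the counts were 249 and 93 (5.87 and 5.45 simulated, 26.0 and 5.65 if independent), with a correlation of 0.552 (0.497 simulated) and a covariance of 0.198 (0.0304 simulated). Part of each excess may come from the shared control, which cannot be split with 1 array.

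**Figure D3:**
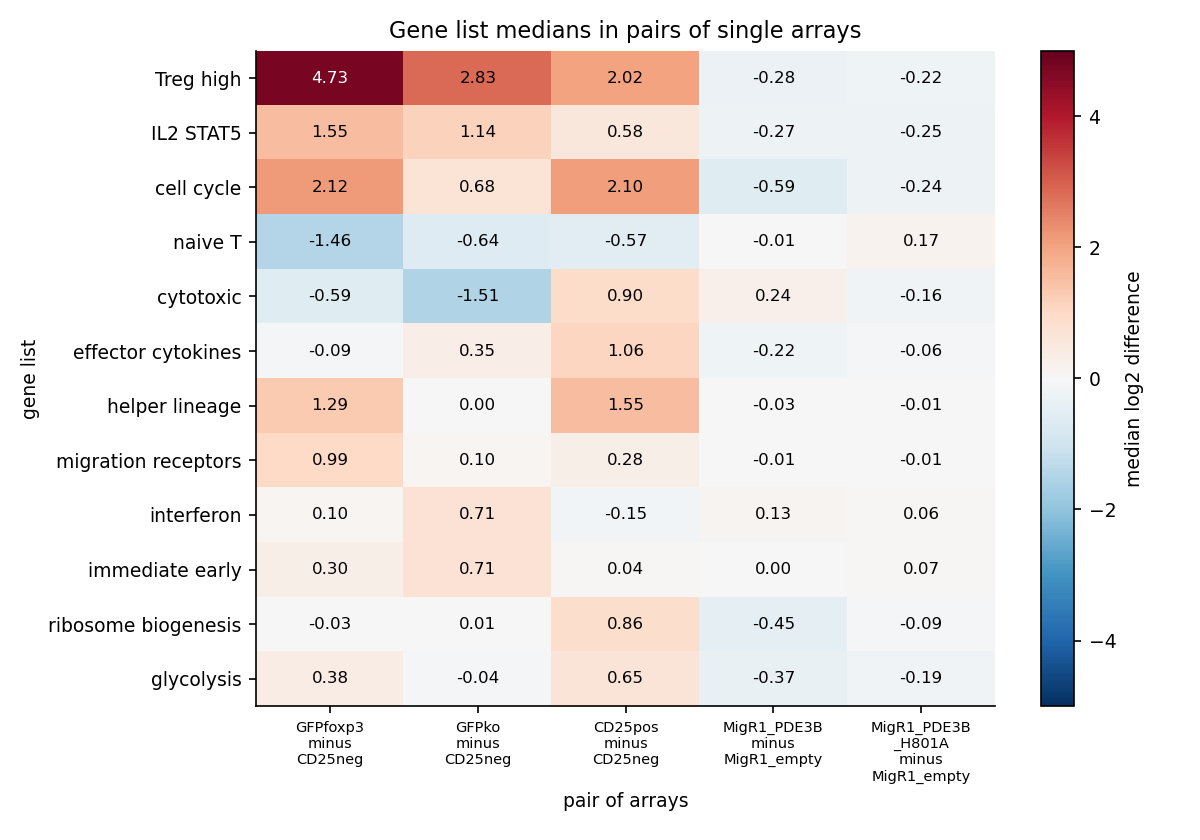
Median log2 difference of 12 gene lists (rows) in 5 pairs of single arrays (columns), coloured from blue (lower) to red (higher). The regulatory T cell list is higher by 4.73, 2.83 and 2.02 in the 3 populations set against CD25neg cells, and the cell cycle list is lower by -0.59 with MigR1_PDE3B.

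Genes of cell division were higher in the arrays of IL-2-treated mice in all 3 populations. Ncapg, a condensin subunit, rose 4.24-fold (log2 change 2.08, SE 0.121, adjusted p = 0.0394), the spindle checkpoint kinase Bub1 3.93-fold (1.97, SE 0.113, adjusted p = 0.0394) and the chromosomal passenger kinase Aurkb 3.60-fold (1.85, SE 0.123, adjusted p = 0.0412), each in 3 of 3 populations. Nuf2 (1.81), Cdca3 (1.76), the spindle motor Kif11 (1.76), Cdca5 (1.74) and the kinase Ttk (1.70) followed. Of the 29 cell cycle genes 7 rose and 0 fell (26 and 0 adjusted over the list alone, median 1.48), and Cdk1, at 2.12 (SE 0.219, adjusted p = 0.102), was among those that did not pass singly. Camera gave the list an adjusted p = 5.9e-32, and adjusted p = 0.409 with an estimated correlation. The list's median was 1.36 in GFPfoxp3, 1.51 in GFPko and 1.32 in CD25pos cells, and all 29 genes were above 0 in GFPfoxp3 and in CD25pos and 27 in GFPko, where Mcm4 and Mcm6 lay below it. Beside this, the Actb 3′ to 5′ difference of these populations moved with IL-2 by -0.369, -0.927 and -0.941 in GFPfoxp3, GFPko and CD25pos.

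Among 19 targets of IL-2 and STAT5 signalling, Cish, which restrains this pathway, rose by 1.07 (SE 0.0763, adjusted p = 0.0473), 1 gene against 2 adjusted over the list alone. The list's median was 0.48 and its adjusted p was 0.00703, and adjusted p = 0.900 with an estimated correlation. Lta, a cytokine of the TNF family, differed by 1.71 (SE 0.615, adjusted p = 0.47) and did not pass. Rgs1, a regulator of G protein signalling counted among the cAMP-responsive genes, rose by 1.69 (SE 0.115, adjusted p = 0.0423), 1 of 12 of its list (1 adjusted over the list alone). Cytotoxic genes held no single call (2 higher adjusted over the list alone), with Gzmb at 1.63 (SE 0.238, adjusted p = 0.175, below the array median on 1 of the 3 untreated arrays) and a list median of 0.36 (adjusted p = 0.0199, and adjusted p = 0.850 with an estimated correlation). Immediate early genes also held none (0 adjusted over the list alone), with a median of -0.18 (adjusted p = 0.0219, and adjusted p = 0.850 with an estimated correlation). Pde3b differed by -0.16 in GFPfoxp3, -0.30 in GFPko and 0.01 in CD25pos cells with IL-2. Limma called 28 genes higher and 0 lower, with 781 and 480 at an unadjusted p under 0.05, and 78 genes were at least 2-fold higher in all 3 populations and 0 lower. With CD25pos, GFPfoxp3 or GFPko cells left out limma called 0 genes (975, 885 and 1160 at an unadjusted p under 0.05), and with quantile normalization, with all genes tested, with a variance trend or without population in the model it called 0 as well (1267, 1520, 1124 and 474).

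**Figure D4:**
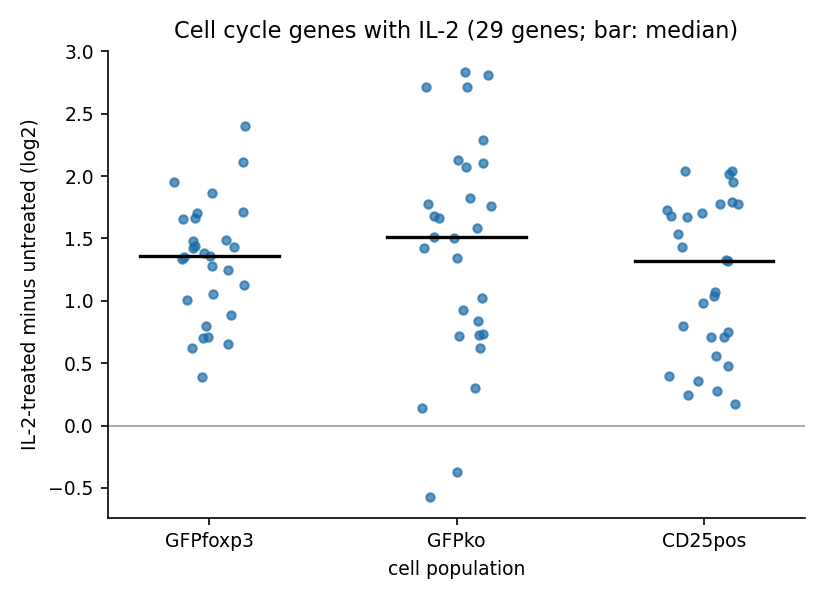
Log2 difference between IL-2-treated and untreated arrays for each of 29 cell cycle genes in 3 cell populations, 1 point per gene, with bars at the medians of 1.36, 1.51 and 1.32. In GFPko cells 27 points lie above 0 and in the other populations all 29.

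Taken as single pairs of arrays, IL-2 went with 207 genes at least 2-fold higher and 26 lower in GFPfoxp3, 348 and 239 in GFPko and 119 and 42 in CD25pos cells. In GFPfoxp3 cells the DNA repair nuclease Eme1 (2.5), the growth factor Hbegf (2.46), Cenpi (2.45), Ckap2 (2.42), the mitotic kinase Plk1 (2.40) and Anln (2.37) were highest, and 4933438K21Rik (-1.99), Tbx20 (-1.95), Gm9222 (-1.88), Defb1 (-1.85), Stox2 (-1.66) and Ebf3 (-1.65) lowest, where Tbx20 turned to 0.032 when dim genes were kept. In GFPko cells Pdlim4 and Lta (3.47 each), the cytokine Lif (3.07), Pstpip2 (3.06), the gamma chain variable segment Trgv1 (2.99) and Spag5 (2.96) were highest. Ifi202b (-3.17), the chemokine receptor Cxcr4 (-2.79), the mTORC1 inhibitor Ddit4 (-2.75), 4933438K21Rik (-2.34), Plekhf1 (-2.29) and Stx1a (-2.06) were lowest, and Il17a was lower by -1.69. In CD25pos cells Depdc1b (3.23), Cdkn3 (2.39), Ncapg (2.27), Gzmb (2.27), Gzma (2.21) and the mitotic ubiquitin enzyme Ube2c (2.16) were highest and Snai3 (-2.04), Nr6a1 (-1.54), Gm36723 (-1.54), Hspa1b (-1.42), Scarb1 (-1.38) and Lad1 (-1.33) lowest, with Scarb1 at 0.053 in probe sets that do not cross-match. Of these genes, Cenpi, Ebf3, Eme1, Hbegf and Tbx20 in GFPfoxp3, Ifi202b, Pdlim4, Pstpip2 and Spag5 in GFPko and Nr6a1 in CD25pos lay below the median of the array on their lower side. Their differences rest on background and their order is not settled. In turn they amount to at least 4.55-, 3.02-, 3.87-, 5.41- and 2.33-fold, 8.15-, 9.75-, 5.27- and 4.49-fold, and 2.29-fold. Targets of IL-2 and STAT5 were higher by a median of 0.93 in GFPko (100th percentile), with Myc at 2.10 and Il2ra at 1.70, and by 0.21 in GFPfoxp3 (99.97th percentile), but had a median of 0.00 in CD25pos (53.1st percentile). In the same GFPko pair markers of myeloid cells had a median of 0.65 (99.98th percentile, 0.55 when centred), with Lyz2 at 2.34, and cytotoxic genes 0.73 (99.99th percentile), with Ccl5 at 2.43. The median level of the myeloid markers was 3.02 untreated and 3.42 after IL-2, against array medians of 3.11 and 3.06. The myeloid shift therefore rests in part on background. CD8 and NK cell markers had a median of -0.16 in the CD25pos pair (1.4th percentile), and cytotoxic genes 0.24 (99.88th percentile). Centring changed the GFPko split to 270 higher and 312 lower (46.4% higher against 59.3%), with an all-gene median of -0.112, and the mean over all probe sets gave 72.6% higher. Across genes the changes correlated at 0.397 between GFPfoxp3 and GFPko, 0.403 between GFPfoxp3 and CD25pos and 0.316 between GFPko and CD25pos.

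The transduced cells ask what PDE3B from a vector does to regulatory T cells, in which its transcript was low. In the array labelled PDE3B, whose own PDE3B level is unverified, the heat shock gene Hspa1b was higher than with the empty vector by 4.51, followed by the histone gene H3f3b (3.09), the IL-6 receptor chain Il6ra (2.95), Jun (2.38), Ankrd29 (2.29) and Dapk1 (2.24). Scin, an actin-severing protein (-3.36), Prkcz (-3.15), the translation factor subunit Eif2b1 (-3.06), Jak3, the kinase of the shared cytokine receptor chain (-2.62), Cby1 (-2.59) and Dusp3 (-2.57) were lowest. Cell cycle genes had a median of -0.59, at the 0th percentile of matched random lists, with 7 of 29 at least 2-fold lower and 0 higher, led by Aurka (-1.67), Plk1 (-1.64) and Cenpe (-1.64). Ribosome biogenesis genes had a median of -0.45 (0.21st percentile), with Srm at -1.25, and glycolysis genes -0.37 (0.94th percentile), with Pkm at -1.88 and Hk2 at -1.31. Interferon genes (0.13, 99.67th percentile) and cytotoxic genes (0.24, 99.57th percentile) lay above random lists, with the chemokine Ccl4 at 1.92 and Gzma at -1.74. Regulatory T cell genes had a median of -0.28 (3.21st percentile), with Tnfrsf9 at -1.23 and Penk at -1.20. Foxp3 differed by -0.26.

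With H801A, Il6ra (3.04), Ankrd52 (2.86), Hspa1b (2.82), Gpr160 (2.37), Tbrg3 (2.24) and the cholesterol exporter Abca1 (2.22) were highest relative to the empty vector, and Ifitm1 (-3.34), Ica1 (-2.73), Gzma (-2.44), Prkar1b (-2.43), Arhgef5 (-2.37) and Supt3 (-2.27) lowest. Prkar1b turned to 0.008 without probe sets that can cross-match. The cell cycle median was -0.24 (0.31st percentile) with 1 of 29 genes at least 2-fold lower, the regulatory T cell median -0.22 (0.48th percentile) and the naive T cell median 0.17 (99.67th percentile). Markers of other cells moved with this pair, plasma cell markers by a median of -0.51 (0.12th percentile, -0.42 when centred), with Mzb1 at -1.74 (at background with H801A, at least 1.68-fold lower), and B cell markers by -0.37 (0.54th percentile, -0.27 when centred), with 0 of 8 at least 2-fold lower and 1 higher, Cd79b being at -0.60 and Cd22 at 1.05. Of the plasma cell list only 4 genes were measured. Their median level was 3.73 with the empty vector and 3.14 with H801A, against array medians of 3.18 and 3.17. The plasma cell shift therefore rests in part on background. Set directly against H801A, the PDE3B array was higher in Ifitm1 (2.59), Selenom (2.46), the kinase Yes1 (2.45), Fos (2.40), Akr1c18 (2.17) and Zc2hc1a (2.07), and lower in Scin (-2.51), Hdac10 (-2.24), Pacs2 (-2.24), Xdh (-2.23), Slc25a30 (-2.19) and Thap11 (-2.16). Among the genes named for the vectors, Dapk1, Dusp3, Eif2b1, H3f3b, Prkcz and Scin (PDE3B against empty), Ica1, Mzb1, Prkar1b and Supt3 (H801A against empty) and Akr1c18, Pacs2, Scin, Selenom and Slc25a30 (PDE3B against H801A) lay below the median of the array on their lower side. Their differences rest on background and their order is not settled. In turn they amount to at least 2.81-, 3.03-, 5.87-, 8.25-, 7.2- and 6.93-fold, 5.67-, 1.68-, 4.22- and 4-fold, and 2.78-, 3.04-, 3.84-, 3.99- and 3.27-fold. With PDE3B against H801A the cell cycle list had a median of -0.31 (0.19th percentile), ribosome biogenesis -0.35 (0.09th percentile) and glycolysis -0.24 (1.76th percentile). Cytotoxic genes were higher by 0.62 (100th percentile), with Gzmk at 1.36 and Ccl5 at 0.90.

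PDE3B differed from the empty vector at least 2-fold in 143 higher and 507 lower genes, H801A in 111 and 163, and PDE3B from H801A in 88 and 275. The Actb 3′ to 5′ difference was highest in the PDE3B array (6.38, against 5.87 with the empty vector and 5.95 with H801A). Centred on their medians, the arrays gave 291 higher and 287 lower genes for PDE3B (50.3% higher against 22.0%), 152 and 122 for H801A (55.5% against 40.5%) and 152 and 199 between them (43.3% against 24.2%), and the all-gene median of PDE3B against the empty vector moved to 0.164. The PDE3B list medians were then -0.37 for cell cycle, -0.24 for ribosome biogenesis, -0.16 for glycolysis, 0.34 for interferon, 0.46 for cytotoxic and -0.07 for regulatory T cell genes. Those of H801A became -0.15 for cell cycle, -0.12 for regulatory T cell and 0.27 for naive T cell genes, and between PDE3B and H801A they became -0.19 for cell cycle, -0.23 for ribosome biogenesis, -0.12 for glycolysis and 0.74 for cytotoxic genes. Because both vectors were compared with 1 empty-vector array, part of their overlap of 45 higher and 97 lower genes may come from that array. Simulated unchanged groups shared 6.20 and 5.96 and independent lists would share 1.33 and 6.92. The simulated spread was that of the 6 modelled arrays of sorted cells. The spread of the vector arrays is unknown and may be larger, so the simulation cannot settle how much of the overlap exceeds it. The correlation across genes was 0.575 (0.501 simulated) and the covariance 0.102 (0.0307 simulated).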

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

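Of the tests given here, those of RNA integrity for the cell cycle genes and of array scale for the PDE3B array were chosen only after the result was seen.

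With IL-2, 28 genes were called over 3 populations, 7 of them in the cell cycle list. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many, the real one, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split had 1261 genes, while 2 others had 2615 each. Those 2 set only the GFPko arrays apart within a population and, with population in the model, are the same contrast. The splits that set only GFPfoxp3 or only CD25pos arrays apart repeat each other likewise, so fewer than 10 are distinct. In the other splits an IL-2 change shared by the populations enters the residual, so their 0 calls decide little. These 10 splits are also too few for a share under 0.05. RNA integrity that moved with IL-2 is one candidate explanation of the rise in cell cycle genes. It would need the rise to follow the move in the Actb 3′ to 5′ difference. In GFPfoxp3 cells that move was 0.392 of that in CD25pos cells, whereas the rise was 1.03 times that in CD25pos cells. A bootstrap over the list's genes gave 0.827 to 1.70, which measures no spread between arrays. The Gapdh 3′ to 5′ difference, untreated and after IL-2, was 5.55 and 5.53 in GFPfoxp3, 5.939 and 5.265 in GFPko and 6.43 and 5.24 in CD25pos. That the rise would scale with these moves was assumed and not tested, and the spread of these single arrays is unknown. Under that assumption the values argue against RNA integrity as the whole source. IL-2 itself stays open, untested between animals.

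For the genes that differ between GFPfoxp3 and GFPko cells, strain variants left around the tagged alleles or by the backcross could be a source, and such variants would place called genes next to each other. Called genes had a called neighbour of the same direction in 13.5%, 1.53 times the 8.79% of shuffled genes (spread of the ratio 0.15), which is no more than the 1.84 times (spread 0.133) of GFPfoxp3 against CD25pos, a comparison within 1 mouse line. Called genes thus lay together no more than within 1 line. Since they also lie together there, the ratio cannot tell what share of the differences variants made. Calls rest on both pairs of arrays, so the ratio could also miss variants present in 1 array only. The 2 GFPko arrays differed in Ifi202b, at 6.09 untreated and 2.92 after IL-2, and the cause of this was not tested. GFPko against CD25pos, also between lines, had a ratio of 2.61 (spread 0.348), so variants stay open for both comparisons between lines. Foxp3 protein, the difference the design names, stays open as well, untested between animals.

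The PDE3B array held 507 genes at least 2-fold lower and 143 higher than the empty vector. RNA integrity remains a candidate explanation: the 275 genes lower in PDE3B than in H801A also had a median of -0.562 in the empty vector against GFPfoxp3 cells, arrays that differ in the Actb 3′ to 5′ difference the same way, at the 0th percentile of 10000 matched random lists (-0.158 to 0.037), so its percentile was 0. The empty-vector and GFPfoxp3 arrays also differ in transduction, in transfer into other mice and in Xist and Y-linked transcripts. The low median therefore cannot be assigned to RNA integrity. Whether the scale of the arrays made the imbalance cannot be told apart from the other sources. Centring sets the balance itself and moved the median of all genes from -0.052 to 0.164, so the 50.3% higher among the 578 genes it left at least 2-fold apart decides nothing. What PDE3B does in the cells, and whether the vector raised it, stays open and cannot be weighed with 1 array per vector.

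Changes with IL-2 that went opposite ways in 2 populations drew attention, and none of these differences was tested. Ribosome biogenesis genes had a median of -0.12 in GFPfoxp3 and 0.35 in GFPko, a difference of -0.47. In CD25pos they stood at -0.43, a difference of 0.78 from GFPko. Regulatory T cell genes had a median of 0.46 in GFPko and -0.14 in CD25pos, a difference of 0.60. Ddit4 was lower by -2.75 in GFPko and higher by 1.16 in CD25pos, a difference of -3.91. In the control probe sets, outside the genes compared, the Actb 3′ to 5′ difference reached 6.38 with PDE3B against 5.87 with the empty vector.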

How the results depend on the processing

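Counting genes at least 2-fold apart the same way in every pair was chosen after seeing the data, all other alternatives before. The cause of these changes was not tested, with exceptions that follow from the settings. A test over all genes adjusts over more genes, and a fit without 1 population has fewer residual degrees of freedom. A higher fold threshold passes fewer genes. For IL-2 (28 genes) quantile normalization called 0 (1267 at an unadjusted p under 0.05), no filter on dim genes 0 (1520), an intensity trend with robust variance 0 (1124) and no population term 0 (474), while centring called 121, the filter on the mean 54, both holding all 28 genes, and 78 were 2-fold higher in every pair. For GFPfoxp3 against GFPko (892) no filter called 382, centring 1379 and every pair 535. For GFPfoxp3 against CD25pos (1042) no filter called 609 and every pair 607. For GFPko against CD25pos (416) no filter called 33 and centring 864. With 1 population or IL-2 state left out, the lone arrays being assumed to vary like the rest, the counts were 0 to 0 for IL-2, 181 to 188, 238 to 260 and 9 to 13 for these contrasts in turn. In single pairs a 3-fold threshold left 613, 325 and 306 genes for GFPfoxp3, GFPko and CD25pos against CD25neg, 64, 127 and 35 for IL-2 in GFPfoxp3, GFPko and CD25pos, and 126, 53 and 61 for PDE3B and H801A against the empty vector and PDE3B against H801A. With the spread borrowed from the 6 modelled arrays, limma called 259 for GFPko and 238 for CD25pos against CD25neg and 0 in each of the 3 IL-2 and 3 vector comparisons (393, 968, 335, 2347, 1374 and 1683 at an unadjusted p under 0.05). The mean of all probe sets gave 391 for IL-2 in GFPko. Of the genes named, 3 turned: Tbx20 with IL-2 in GFPfoxp3 to 0.032 without the filter, and, without cross-matching probe sets, Scarb1 with IL-2 in CD25pos to 0.053 and Prkar1b with H801A to 0.008. Of the other results for named genes 935 were the same, 47 weaker and 42 moved, and of those for lists 333 were the same, 42 weaker and 9 stronger. The other pseudocount planned for a linear table was not run, as the values are log2. Probe sets near the background of about 3 log2 units limit what can be seen as lower.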

Other observations

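The values in this part were chosen after the data were seen, apart from the gene lists. Some transcripts of other lymphocytes were looked up in the untreated sorted cells. Zbtb16, which encodes PLZF, lay at 6.44 in CD25pos and at 3.73 in CD25neg, 2.56 in GFPko and 2.5 in GFPfoxp3 cells, and the gamma chain segment Trgv4 at 9.43 against 5.04, 8.48 and 5.83, so that Trgv4 was also abundant in GFPko cells. Klrd1 was at 8.91 in CD25pos and 8.88 in CD25neg cells but at 3.04 in GFPko and 2.86 in GFPfoxp3 cells. Gbp2b lay at 2.60 to 2.61 in the 3 GFP-negative arrays and at 7.96 to 9.33 in the 7 GFP-positive ones, GFPko cells included. Foxp3 transcript divided the arrays the same way (2.45 to 3.90 against 8.33 to 11.52). Gbp2b thus went with GFP or Foxp3 transcript rather than with Foxp3 protein. GFP marks the locus in the sorted cells and the vector in the transduced ones. Ifi202b, an interferon-inducible gene, was at 6.09 in untreated GFPko cells and at 2.92 in GFPko cells after IL-2, and lay between 2.74 and 2.98 in the other 8 arrays.

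The genes that differ with Foxp3 protein were looked up in the transduced cells. The 650 genes higher in GFPfoxp3 than in GFPko cells had a median of -0.213 with PDE3B against the empty vector (0th percentile of matched random lists, 5 genes at least 2-fold higher and 62 lower), -0.114 with H801A against the empty vector (0th percentile, 7 and 16) and -0.104 with PDE3B against H801A (0.28th percentile, 8 and 35). The 242 genes lower in GFPfoxp3 cells had medians of 0.004, 0.001 and -0.007 in these comparisons, at the 100th, 99.7th and 98.32nd percentiles. All of these share the limits given for the vector arrays. Il6ra lay at 5.87 with the empty vector, 8.82 with PDE3B and 8.91 with H801A, and between 9.16 and 10.19 in the 7 arrays of sorted cells.

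Of the 24 gene lists, 11 were called by camera at the preset correlation in none of the 4 modelled contrasts. Their lowest camera adjusted p was 0.0814 for cAMP-responsive genes, 0.0878 for helper lineage factors, 0.123 for cholesterol synthesis, 0.154 for the X-linked neighbours of Foxp3, 0.221 for cAMP machinery, 0.233 for apoptosis and for B cell markers, 0.248 for erythroid markers, 0.349 for inhibitory and activation receptors, 0.397 for T cell receptor signalling and 0.45 for plasma cell markers. Fry, which compares a list with no other genes, called 3 of these 11. They were inhibitory and activation receptors in GFPfoxp3 against GFPko (adjusted p = 0.0181), GFPfoxp3 against CD25pos (0.017) and GFPko against CD25pos (0.0448), B cell markers in the first (0.0181) and second (0.017) of these contrasts, and apoptosis in the first (0.0245). Single members still passed, and Cxcr5, the receptor for B cell follicles, was 3.69 higher (below the array median on 1 of 2 GFPko arrays) and Il18r1 3.42 lower (log2 difference -3.42) in GFPfoxp3 than in GFPko cells. Among lists, centring the arrays moved helper lineage factors in that comparison to an adjusted p = 0.0106 and effector cytokines in GFPko against CD25pos to an adjusted p = 0.0347, and moved the myeloid markers from 0.039 to 0.0525 (0.0822 with quantile normalization).

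The labels describe the transduced cells as female. Xist, the transcript of the inactive X chromosome, was at 12.61 to 12.81 in the 7 arrays of sorted cells and at 3.91, 3.31 and 3.94 in the empty, PDE3B and H801A arrays. The Y-linked genes Eif2s3y (9.55, 9.95 and 9.65) and Kdm5d (8.31, 8.48 and 8.57) were high in these 3 arrays and at 3.01 to 3.19 and 2.39 to 2.48 in the sorted cells. Of the 4 probe sets of the Y-linked gene Uty, 1 lay at 5.49, 7.30 and 5.77 and another at 2.67, 4.09 and 2.68 in the empty, PDE3B and H801A arrays, so Y-linked transcripts were not all at one level within the vector arrays.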
